A study of Caenorhabditis elegans with 2 samples.

How the data were processed

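Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole young adult Caenorhabditis elegans, collected 66 hours after synchronisation from starved first-stage larvae. The worms carried an integrated fosmid transgene that expresses the RNA-binding protein RBM-26, the product of rbm-26 (sequence name B0336.3), fused to GFP, together with a functional unc-119 gene as the rescue marker in an unc-119 mutant background. Per the labels, an antibody against GFP was used, chromatin was sheared by sonication to fragments of 200 to 800 bp, and the 2 libraries are biological replicates 1 and 2 of 1 group. There is no second group, so no condition was compared with another. A control experiment is named as possible in the labels and was not analysed here.

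The authors deposited peak lists on the genome assembly ce11, per the labels and the accompanying notes. The aligner, the peak caller and the number of reads per library are not given in the sources used here, so the depth behind each list is unknown. Each replicate has its own list thresholded on the irreproducible discovery rate (IDR) and its own longer ranked list. The whole series has a conservative thresholded list, a wider thresholded list and 2 ranked lists made from both replicates. All 3045 rows of the conservative list were found in 1 of these ranked lists, called the between-replicate list here. Of the pairs of intervals that this list gives, 90.4% of the first and 85.3% of the second matched an interval in the ranked list of replicate 1 and of replicate 2. The wider list matched the other ranked list, called the pooled list here. All thresholded rows had a deposited −log10 global IDR of at least 2, which is a global IDR of 0.01. The deposited lists left out 3 rows of the conservative list, 5 of the wider list, 5 of replicate 1 and 2 of replicate 2 that also met this value. The signal of a peak is the authors' own deposited value for that peak and was used only to rank or describe regions within a list. The deposited score per peak is capped at 1000 and was not used in a test. The deposited −log10 q-values were not used in a test, and the p-value column holds no values. The highest interval end on each chromosome did not exceed the length of that chromosome in the reference sequence, which was taken with the Ensembl 115 annotation.

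Overlapping rows of a list were merged to 1 region that kept the summit and signal of its row of highest signal. Regions on the 6 nuclear chromosomes entered the tests. The conservative list was the main list. Each summit was given 1 annotation class, the first that applied. The order was within 500 bp upstream of a gene start, coding exon, 5' UTR, 3' UTR, exon of a non-coding gene, intron and intergenic. Exons of pseudogenes were counted with those of non-coding genes. Shares of summits by class, near starts and ends of protein-coding genes (500 bp), and the number of non-coding genes with a summit within 250 bp were compared with 1000 random placements on the same chromosome. These are permutation tests of position. They were two-sided and can give no p below 0.002, and for the overlap of replicates they were one-sided and can give no p below 0.001. Annotated starts of trans-spliced genes lie at the trans-splice site and not at the site of initiation. A protein-coding gene was called bound where its start was the nearest to a summit and within 1000 bp. Bound genes of 28 gene lists were compared with the other protein-coding genes by two-sided Fisher's exact tests, with 95% intervals of the odds ratio computed with 0.5 added to each cell. Symbols of 375 genes were taken from RefSeq, and 3 named list members were not found in the annotation. The 28 lists were cytosolic and mitochondrial ribosomal proteins, translation factors, splicing and snRNP, RNA exosome and nuclear RNA decay, mRNA 3' end processing, histones, vitellogenins, cuticle collagens, vacuolar ATPase, proteasome, respiratory chain and ATP synthase, heat shock proteins, chemosensory receptors, nuclear hormone receptors, homeobox genes, C-type lectins, F-box proteins, xenobiotic enzymes, germline mitosis and meiosis, oocyte and early embryo, sperm, muscle, intestine, epidermis, neurons, pharynx, and stress and longevity regulators. Chromosome shares were compared with chromosome lengths by exact binomial tests. The GC content of the 101 bp at each summit was compared with the mean of its flanks 500 bp away by a sign-flip permutation test with 100000 draws, and each 6-mer by an exact McNemar test against 1 flank drawn at random. Genes within 500 bp downstream of the end of a same-strand gene were taken as candidate downstream genes of operons. Their share of bound genes was compared with 1000 random placements, 1000 draws from the ranked list, and 1000 moves of the summits within 500 bp of a gene end to the same place at a random gene end of the chromosome. All adjusted p-values are Benjamini-Hochberg values within each family of tests. Regions and genes of a list are not independent replicates, since they cluster along chromosomes, so these p-values describe the lists and not the spread between animals.

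The tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule takes the 20 regions of highest signal with the nearest protein-coding start, the 4 bound members of highest signal in each list with an adjusted p under 0.05 and the 2 of highest signal in each other list, rbm-26, unc-119 and mals-1 in every list, and the 5 most enriched 6-mers. Non-coding genes at the strongest regions and at named genes, neighbours of rbm-26 and symbol families were named after their values were seen. The alternatives were the wider list, each replicate's own list, the 500 regions of highest signal, unmerged rows, other distances, overlaps, windows and IDR thresholds, and a background of ranked sites. Some alternatives were added after the data were seen: leaving out regions of the commonest width of the list, ranked sites as the background for features, distances and non-coding genes, all ranked regions for the signal agreement, ranked regions of the same replicate for the overlap, gene lists without regions at small non-coding genes, 3 backgrounds for the operon candidates, and the other lists for the number of regions and for rbm-26 and unc-119. Decision rules for the explanations weighed in the closing section were written before their tests were run. In a first computation 2 of these rules, both on tRNA genes, were applied in another form than written. Both were put back to the written form after the values had been seen, which changed their verdicts and not the values. The planned placement of regions on ranked regions of either replicate was first computed with the same replicate only and is given in both forms. The test on tRNA genes whose sequence occurs once was added after the tRNA result had been seen. The steps were tested on simulated data of 2416 regions per set. Planting 20% of the summits upstream of gene starts gave 26.6% in that class where 27.5% was to be recovered. All 28 planted members of a list of 70 genes were recovered as bound. With no effect planted, 2 false calls were made over 140 feature tests, 0 over 560 list tests and 1 over 2080 6-mers. In the list tests the simulated summits stood exactly on the starts of genes drawn at random. Recovery of the planted members was therefore fixed in advance. The false calls over lists do not cover distant summits, gene spacing or clustered families. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.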

Results

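Binding of RBM-26, an RNA-binding protein and the worm ortholog of human RBM26 and RBM27, was profiled by ChIP-seq against its GFP tag in whole young adult worms, with 2 biological replicates. The conservative list of the series held 3045 rows, which merged to 2422 regions covering 1.39% of the genome. Of these regions 2416 lay on the nuclear chromosomes. The wider series list held 2643 regions, the list of replicate 1 held 1955 and that of replicate 2 held 1556, a ratio of 1.26 between the replicates. The median row width was 620 bp in the conservative list, 580 bp in replicate 1 and 650 bp in replicate 2, and 47.5% of the conservative rows had exactly the commonest width. The read depth per library is unknown, so a difference in list length between the replicates has no test.

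How far the 2 replicates found the same regions was tested first. Of the 1950 nuclear regions of replicate 1, 58.1% overlapped a region of replicate 2 by at least 1 bp, against 1.80% under random placement (one-sided permutation test of position, p = 0.001, the smallest that 1000 placements can give). Of the 1546 nuclear regions of replicate 2, 72.6% overlapped replicate 1, against 2.28% under placement (the same permutation test, p = 0.001). With regions drawn from the ranked regions of either replicate, the chance overlap was 8.45% and 10.5%, and with those of the same replicate 7.63% and 11.8%. Of the 817 regions thresholded in replicate 1 alone, 94.7% overlapped a ranked region of replicate 2, against 24.6% under placement. Of the 424 in replicate 2 alone, 87% overlapped a ranked region of replicate 1, against 28.0% under placement. Of the 2416 nuclear regions of the conservative list, 45.4% overlapped a region in the lists of both replicates, 22.4% in that of replicate 1 alone, 9.31% in that of replicate 2 alone, and 553 (22.9%) in neither. The deposited signals of both replicates over 2402 matched regions had a Spearman rho of 0.622 (95% block bootstrap interval 0.592 to 0.650) and a Pearson r of 0.711 on the log10 scale. The conservative regions had passed a threshold on agreement between the replicates, so this value is not free of selection. Over all ranked between-replicate regions, 13066 of 17826 were matched, with a rho of 0.641 (0.628 to 0.654). These correlations are across regions, which are not independent replicates.

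All 20 regions of highest signal were in the lists of both replicates, 14 of them within 1000 bp of a protein-coding start and 7 within 250 bp of a non-coding gene. The highest signal, 619, stood on chromosome X (14525478 to 14526222), 738 bp upstream of nspc-17. It was followed by a signal of 607 on chromosome III (13643477 to 13644012), 154 bp upstream of drr-2, and another of 607 on III (10758976 to 10759590), 43 bp upstream of tasp-1. The region on I (4171757 to 4172900) had a signal of 607 and lay 626 bp upstream of egg-5. Its summit was inside the ncRNA gene R12E2.18 and within 250 bp of the spliced-leader RNA gene sls-2.4. Ribosomal protein genes rpl-3 (signal 595), rpl-35 (558) and rpl-15 (554) had summits 292, 457 and 358 bp upstream of their starts. Summits lay upstream of Y22D7AL.10 (signal 576, 164 bp), Y17G9B.5 (553, 155 bp), tag-340 (542, 590 bp), wip-1 (534, 307 bp), Y55F3AR.2 (527, 196 bp) and Y54G11A.2 (517, 776 bp). The summit near ZK1248.17 (signal 568) was 722 bp downstream of its start, past the end of this short gene, and 46 bp from sls-2.1. In the other 6 regions the nearest start was more distant, at 4779 bp for cmd-1 (signal 606, within the long non-coding RNA linc-128), 3967 bp for W02H3.3 (591), 3378 bp for cest-16 (568), 6992 bp for ppfr-1 (566), 3490 bp for F58G1.7 (561, 35 bp from the snRNA gene sup-6) and 15208 bp for C41A3.2 (531).

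Summits were concentrated just upstream of gene starts and thinned out in gene bodies. Of the 2416 summits, 31.1% (95% Wilson interval 29.3 to 33) lay within 500 bp upstream of a gene start, against 9.42% under random placement, a 3.30-fold difference. Untranslated regions and non-coding exons, with those of pseudogenes included, were also over-represented. Of the summits 2.90% lay in 5' UTRs (2.24-fold), 5.38% in 3' UTRs (1.94-fold) and 7.24% in non-coding exons (2.38-fold). Introns held 15.9% against 33.9%, coding exons 15% against 24.1%, and intergenic sequence 22.5% against 25.5%. All 7 classes differed from placement (adjusted permutation p = 0.0023 for 6 classes and 0.0040 for intergenic). Among the 500 regions of highest signal 5' UTRs, 3' UTRs and intergenic sequence were not past the threshold (adjusted permutation p = 0.073, 0.19 and 0.88). The intergenic class was not past the threshold in replicate 2 alone (0.976-fold), and it turned to 1.47-fold when sites were drawn from the ranked list. Against such sites the upstream class fell to 2.18-fold, with 14.3% drawn, 5' UTRs had 1.51-fold, 3' UTRs 1.49-fold, non-coding exons 2.11-fold, introns 0.553-fold and coding exons 0.458-fold.

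**Figure D1:**
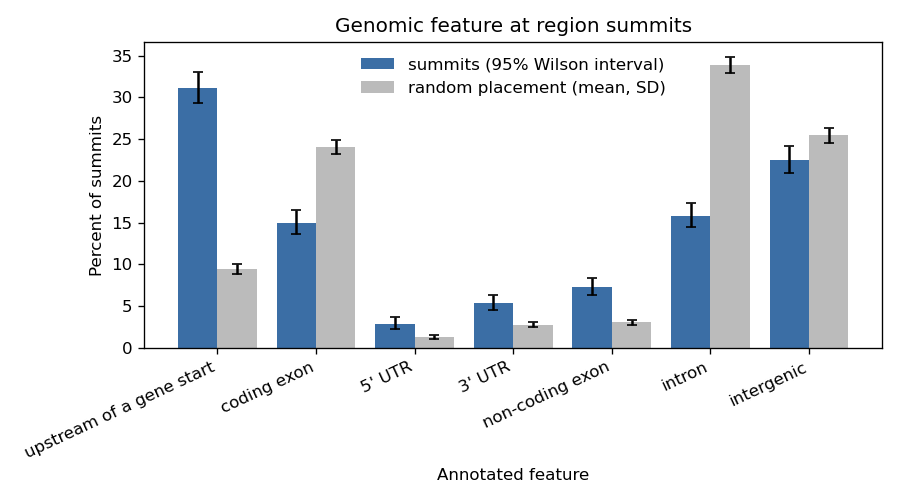
Percent of the 2416 nuclear summits in each annotation class (blue, with 95% Wilson intervals) beside the mean and SD of 1000 random placements (grey). The class upstream of gene starts stands at 31.1% against 9.42%, and introns at 15.9% against 33.9%.

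Both ends of protein-coding genes had nearby summits. Within 500 bp of a start lay 42.5% of summits (95% Wilson interval 40.6 to 44.5) against 18.7% under placement, and within 500 bp of an end 43.0% (41.0 to 44.9) against 17.1% (adjusted permutation p = 0.002 for both, the smallest possible). The densest bins of 100 bp were 200 to 100 bp upstream of the nearest start, with 213 summits against 45.5 under placement, and 100 to 200 bp downstream of the nearest end, with 328 against 45. Against sites drawn from the ranked list, the excess was 1.66-fold near starts and 1.73-fold near ends. Gene ends over 1000 bp from any annotated protein-coding gene start still had 17.3% of summits against 8.55%, or 2.02-fold. This was 1.75-fold in replicate 1 and 2.32-fold in replicate 2.

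**Figure D2:**
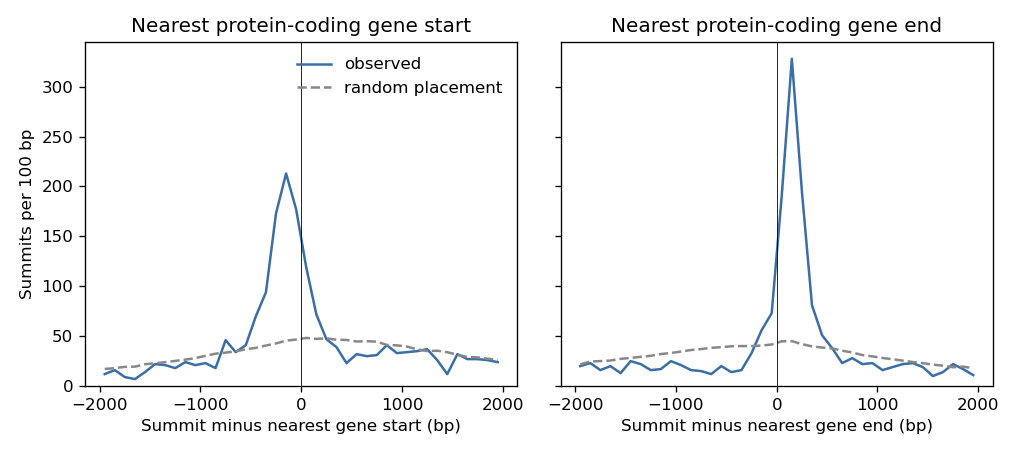
Number of summits per 100 bp by distance from the nearest protein-coding gene start (left) and gene end (right), in bp with negative values upstream, observed (blue) and the mean of 100 random placements (grey, dashed). The observed curve reaches 213 just upstream of starts and 328 just downstream of ends.

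In the conservative list chromosome III was the densest and X the sparsest. III had 31.8 regions per Mb (1.32 times its share by length, adjusted exact binomial p = 5.1e-09), I had 27.9 (1.16, adjusted exact p = 0.0023), V had 19.6 (0.813, adjusted exact p = 3.0e-06) and X had 17.4 (0.721, adjusted exact p = 3.9e-10). II (26.2, adjusted exact p = 0.099) and IV (25.1, adjusted exact p = 0.40) were not past the threshold. Chromosome I was not past it in the list of replicate 1 (1.12, adjusted exact p = 0.054), and IV was below its share there (0.967). In that list V was the sparsest, with 15.1 regions per Mb against 16.1 for X. Among the 500 regions of highest signal I (7.03 per Mb) stood above III (6.89), and V (3.25) below X (3.84). Each chromosome was also split in a left, central and right part of equal length. The central part of the autosomes held 39.0% of their regions against 33.3% by length (adjusted exact p = 1.5e-07), and that of X 32.5% (adjusted exact p = 0.76). Among the 500 regions of highest signal the central part of the autosomes held 38.0% and was not past the threshold (adjusted exact p = 0.074). The exact binomial test takes regions as independent, which clustered regions are not.

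The fixed gene lists asked which kinds of gene lay next to a summit. Of 19973 protein-coding genes 1329 (6.65%) were bound, and 12 of the 28 lists were above the background and 4 below it (two-sided Fisher's exact test, Benjamini-Hochberg). The list of replicate 1 gave 8 above and 4 below, and that of replicate 2 gave 7 above and 2 below. Cytosolic ribosomal proteins had 38 of 83 genes bound (odds ratio 12.2, 95% interval 7.90 to 18.8, adjusted exact p = 5.4e-22), with 37 bound in replicate 1 and 36 in replicate 2. With assignment within 500 bp of the start, 20 of the 83 were bound and the odds ratio was 5.96 (adjusted exact p = 7.1e-08). Besides the 3 genes above, rps-13 had a signal of 426, with its summit 811 bp downstream of its start. Many others of the 38 also had their summit over 500 bp downstream of the start. Among them were rpl-38 (985 bp), rpl-31 (880 bp) and rps-27 (783 bp), each past the end of the short gene. Summits assigned to this list were therefore not confined to the upstream side of the genes. Those past the end of a gene may belong to a neighbour. The summit of rpl-38 lay in an intron of another gene, and those of rpl-22 and rpl-32 in a coding exon of another gene. Translation factors had 11 of 39 bound (odds ratio 5.55, adjusted exact p = 0.00018), led by iff-2, an eIF5A gene (signal 370), eif-2Bgamma (359), eif-3.C (358) and eef-1A.2 (301). Mitochondrial ribosomal proteins had 10 of 71 bound (2.31, adjusted exact p = 0.046), led by mrpl-23 (233), mrpl-50 (213), mrpl-32 (202) and mrps-7 (161). The respiratory chain and ATP synthase had 10 of 32 (6.42, adjusted exact p = 0.00018), with the cytochrome c oxidase genes cox-5A (461), cox-5B (349) and cox-6A (261) and atp-1 (293). Oocyte and early embryo genes had 11 of 31 (7.77, adjusted exact p = 2.5e-05), with the RNA-binding proteins puf-11 (283), pos-1 (211) and mex-1 (208) and the yolk receptor rme-2 (196).

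Further lists above the background concerned protein turnover, RNA processing and stress. The vacuolar ATPase had 6 of 20 genes bound (odds ratio 6.03, adjusted exact p = 0.0046; vha-2 271, vha-13 171, vha-17 162, vha-12 157). Stress and longevity regulators had 8 of 30 (5.13, adjusted exact p = 0.0027), among them the kinase gene aak-2 (248), xbp-1 (196), zip-2 (147) and atfs-1 (133). The proteasome had 8 of 33 (4.51, adjusted exact p = 0.0041; rpn-3 214, pbs-5 197, rpn-11 162, pas-1 124). The RNA exosome and nuclear RNA decay had 4 of 17 (4.33, adjusted exact p = 0.046), namely the nuclear exonuclease gene xrn-2 (325), exos-1 (202), nrde-2 (120) and mtr-4 (111.9). Heat shock proteins had 5 of 24 (3.70, adjusted exact p = 0.041; hsp-3 390, hsp-1 284, hsp-17 140, hsp-16.20 133), and splicing and snRNP genes 8 of 42 (3.31, adjusted exact p = 0.015; snr-4 356, rsp-1 207, prp-40 195, snr-6 166). Histones had 11 of 72 (2.54, adjusted exact p = 0.018; his-37 329, his-68 225, his-59 209, his-42 201), a family that lies in clusters. RNA exosome and heat shock genes were past the threshold in neither replicate's own list, histones and the proteasome not in that of replicate 1, and mitochondrial ribosomal proteins, the vacuolar ATPase and stress and longevity regulators not in that of replicate 2. With assignment within 500 bp of the start, mitochondrial ribosomal proteins, the RNA exosome, histones and heat shock proteins were not past the threshold. With sites drawn from the ranked list as the background, 5 of these 12 lists stayed past the threshold. They were cytosolic ribosomal proteins (4.68-fold), histones (3.89-fold), oocyte and early embryo (3.30-fold), respiratory chain and ATP synthase (3.07-fold) and translation factors (2.71-fold). These folds divide the bound members by the drawn ones and are another measure than the odds ratios. All summits lay within 500 bp of a start 1.66-fold more often than ranked sites. The folds do not allow for this, so 1 is not their neutral value.

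Large families of environmental and sensory genes were bound less often. Chemosensory receptors had 10 of 1310 bound (odds ratio 0.101, adjusted exact p = 5.0e-26; sri-5 331, srh-269 270, srw-95 220, srbc-58 208), C-type lectins 5 of 240 (0.296, adjusted exact p = 0.0067; clec-126 259, clec-221 204, clec-87 190, clec-57 148), F-box proteins 8 of 322 (0.354, adjusted exact p = 0.0040; fbxa-83 373, fbxb-85 303, fbxa-202 206, fbxb-72 185) and xenobiotic enzymes 5 of 185 (0.387, adjusted exact p = 0.046; gst-27 233, gst-9 165, gst-1 122, ugt-50 114). F-box proteins and xenobiotic enzymes were not past the threshold in the list of replicate 2, nor xenobiotic enzymes with assignment within 500 bp. None of these 4 was past the threshold against ranked sites. There chemosensory receptors had 1.53-fold, C-type lectins 1.16-fold and F-box proteins 1.47-fold as many bound genes as drawn. These folds can restate the general excess of summits near starts. They do not show that these families were bound more often than other genes. Tissue marker lists did not pass, with 2 of 28 muscle genes (unc-112 147, act-2 103), 1 of 28 intestinal (spp-1 121), 1 of 28 epidermal (wrt-1 90.2), 1 of 33 neuronal (unc-33 113) and 0 of 19 pharyngeal genes bound. Germline mitosis and meiosis had 2 of 42 (cye-1 177, hrde-1 99.6) and sperm 4 of 79 (spe-48 255, spe-15 234). The other lists not past the threshold were nuclear hormone receptors with 10 of 269 (nhr-47 307, nhr-255 194), homeobox genes with 1 of 79 (ceh-38 194), cuticle collagens with 7 of 156 (col-63 283, col-85 179), vitellogenins with 2 of 6 (vit-2 163, vit-6 150) and mRNA 3' end processing with 1 of 15 (cfim-2 245). For mRNA 3' end processing each replicate's own list gave 3 of 15, with odds ratios of 4.41 and 5.41 that were not past the threshold (adjusted exact p = 0.081 and 0.067).

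Some genes named from the lists share their summit with a small non-coding gene. Of the 81 named genes, 18 had their summit within 250 bp of a tRNA, snoRNA, snRNA or miRNA gene, so their signal cannot be assigned to the protein-coding gene alone. Genes annotated as snRNA lay near the summits of hsp-16.20 (F08H9.10, summit inside), clec-57 (F08H9.11, 6 bp), snr-4 (T11F9.15, 19 bp), his-42 (C47F8.9, 20 bp), eif-2Bgamma (sup-39, 23 bp) and cox-6A (F54D8.7, 61 bp). A snoRNA gene lay near those of cfim-2 (12 bp), mrpl-23 (30 bp), gst-27 (31 bp), fbxa-83 (48 bp) and rps-13 (229 bp). A tRNA gene lay near those of col-85 (12 bp), cye-1 (25 bp), nhr-255 (37 bp), clec-126 (45 bp), srh-269 (92 bp) and spe-15 (99 bp), and a miRNA gene near that of mtr-4 (68 bp). Without the 257 regions at such genes, 8 lists were above the background and 4 below it. Mitochondrial ribosomal proteins, RNA exosome and nuclear RNA decay, heat shock proteins and histones were then not past the threshold. The regions of mtr-4, wrt-1 and unc-33 overlapped a region in neither replicate's own list. Those of his-68 and clec-57 overlapped regions of both, but there the 2 genes were not called bound.

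**Figure D3:**
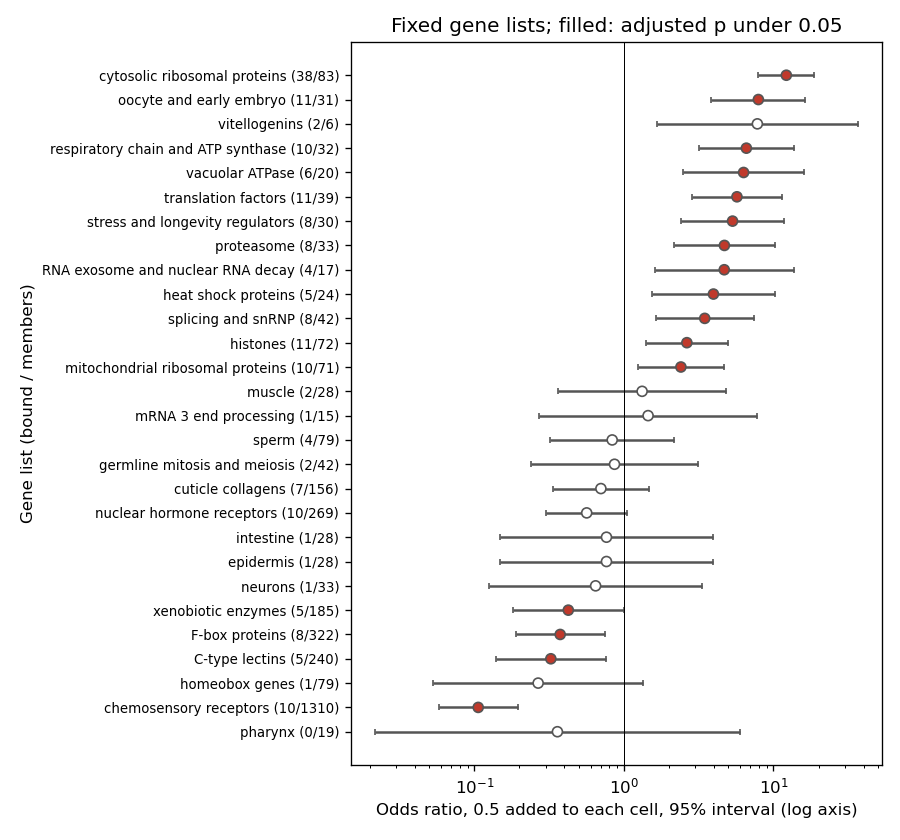
Odds ratio of being bound for each of the 28 gene lists (log axis), computed with 0.5 added to each cell, with 95% intervals; filled points have an adjusted p under 0.05 and labels give bound genes over members. Cytosolic ribosomal proteins (38 of 83) stand highest among the lists past the threshold, and chemosensory receptors (10 of 1310) lowest.

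Non-coding genes were tested by their class in the annotation. A summit lay within 250 bp of 38 of 129 snRNA genes (19.2-fold over placement), 140 of 612 tRNA genes (18.1-fold), 85 of 346 snoRNA genes (15.2-fold), 19 of 261 miRNA genes (5.18-fold) and 462 of 7764 genes of the general ncRNA class (4.02-fold), each with an adjusted permutation p = 0.0030. The list of replicate 1 hit 34 snRNA, 140 tRNA, 81 snoRNA, 14 miRNA and 440 general ncRNA genes, and that of replicate 2 hit 26, 85, 79, 12 and 290. Without regions of the commonest width the numbers were 22, 52, 71, 11 and 263, all still past the threshold. Regions at tRNA, snoRNA, snRNA or miRNA genes numbered 257, or 10.6% of all. The median signal of regions at snoRNA genes was 219.99, against 141 for the other regions. It was 153 against 144 for tRNA genes, 159 against 143 for snRNA genes and 168 against 144 for miRNA genes, and these differences were not tested. The piRNA genes were hit in 22 of 15363 cases (0.111-fold, adjusted permutation p = 0.0030), and with sites drawn from the ranked list this was 0.819-fold and not past the threshold (adjusted permutation p = 0.82). Antisense RNA (6 of 100), lincRNA (8 of 194) and rRNA genes (0 of 20) were not past the threshold. Against ranked sites the excess was 5.01-fold for snRNA, 4.52-fold for snoRNA, 3.51-fold for tRNA, 2.78-fold for miRNA and 2.29-fold for the general class. Of the 612 tRNA genes, 472 share their exact sequence with another.

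Summits were richer in G and C than their surroundings. The central windows had a GC content of 46% ± 8.63 (SD over 2416 regions) and the flanks 36.8% ± 6.65, a difference of 9.26 percentage points (two-sided permutation p = 1e-05, the smallest possible), with the summit higher in 79.3% of regions. The difference was 11.6 points in replicate 1 and 6.42 in replicate 2. Of 2080 6-mers 601 were enriched and 395 depleted. Summit and flank windows were not matched for GC content, so these counts can in part restate the GC difference. The simulated windows held no planted GC difference, so their false calls do not cover this. The 5 most enriched were ACGCAG, found in 12% of summit windows against 1.57% of flanks (adjusted exact McNemar p = 4.6e-48), AGAGAG (16.2% against 3.56%), GAGAGA (18.3% against 5.17%), AGACGC (11.0% against 1.90%) and GACGCA (11.4% against 2.19%), each counted with its reverse complement. ACGCAG, AGACGC and GACGCA overlap one another in sequence, and so do AGAGAG and GAGAGA, so they are not separate motifs. The list of replicate 1 gave 646 enriched and 391 depleted 6-mers, and that of replicate 2 gave 330 and 224.

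The tagged gene had several regions around it and the rescue marker had none. The gene rbm-26 lies on chromosome III from 5711542 to 5714846 on the + strand, and with 20 kb either side it held 6 regions of the conservative list, 9 of the wider list, 7 of replicate 1 and 5 of replicate 2. Of 319 windows of that size on the chromosome, 7 had as many regions of the conservative list and 4 had as much summed length. Among the regions touching the gene the highest signal was 210, in a region from 5714517 to 5715345 that spans its end and the start of arf-1. The highest of the 6 regions, with a signal of 371 from 5705065 to 5705886, spans the end of the ribosomal protein gene rpl-23 and the start of swp-1. No list had a region at unc-119 or within 20 kb of it. The gene mals-1 (chromosome III, 8047712 to 8048464) was included because its regulation by RBM-26 has been reported. It had no region touching it in any list, with 1 region of the conservative list within 20 kb. These are regions on chromatin, so their absence at mals-1 does not speak to regulation at the level of RNA. The strain carries rbm-26 and sequence around it in the transgene in addition to the genomic locus, and the number of copies is not given in the sources used here.

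**Figure D4:**
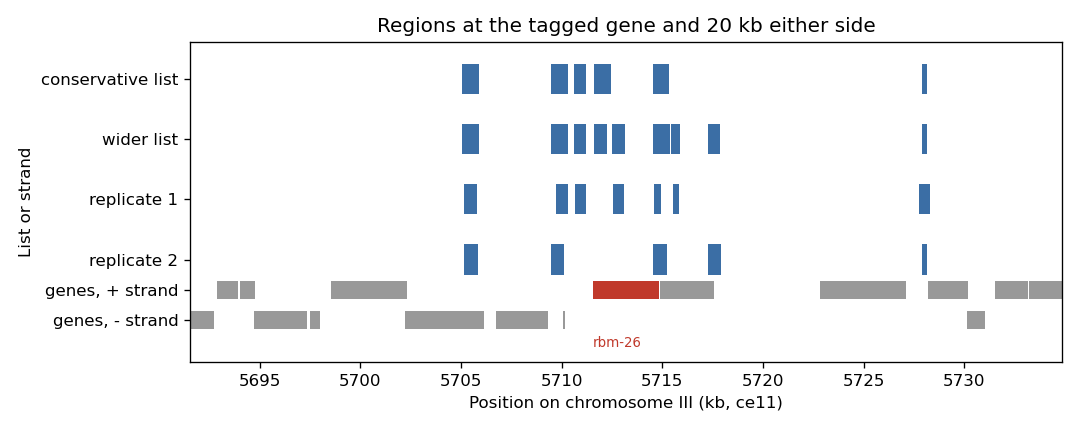
Map of rbm-26 (red) and 20 kb either side on chromosome III in kb, with regions of each list as blue bars and other protein-coding genes in grey by strand. The conservative list has 6 regions with a summit in this window, the wider list 9, replicate 1 has 7 and replicate 2 has 5.

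Candidate downstream genes of operons were bound more often than other genes, but not beyond ranked sites. Of 3618 such genes 10.4% were bound, against 5.83% of the other 16355 (odds ratio 1.87, 95% interval 1.65 to 2.13, two-sided Fisher's exact p = 3.8e-21). The odds ratio was 1.67 in replicate 1 and 1.87 in replicate 2. These genes start close to gene ends, where summits were concentrated too. Candidates made up 28.3% of all bound genes, against 19.1% under random placement and 19.8% with the 1038 summits near gene ends moved to other gene ends (1.48-fold and 1.43-fold, permutation p = 0.002 for both). With sites drawn from the ranked list they made up 28.4% (0.998-fold, permutation p = 0.96), so the thresholded regions had no excess over ranked ones.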

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

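The tests on the nuclear chromosomes left out the mitochondrial genome, which also carried called regions in every thresholded list. The conservative list had 6 mitochondrial regions, the wider list 8, replicate 1 had 5 and replicate 2 had 10. They are given because they lie outside the tested data. No control library was analysed here, so the background level is unknown and these numbers do not separate binding from background. In the conservative list they covered 33.2% of the 13.794 kb mitochondrial genome, against 1.39% of the whole genome covered by all regions. Their median signal there was 359. The share of the mitochondrial genome covered was 30.6% in the list of replicate 1 and 55.5% in that of replicate 2. No explanation was tested.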

How the results depend on the processing

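The alternatives without regions of the commonest width, with ranked sites for features, distances and non-coding genes, without regions at small non-coding genes, with other backgrounds for the operon candidates, and with the other lists for the number of regions were chosen after seeing the data. Of the alternatives set before the data were seen for the results that answer a comparison, 181 kept direction and side of the threshold, or a count within 1.5 times, and of those added later 57 did; the others follow, and the cause was not tested. Shorter lists hold fewer regions. The read depth is unknown, so what it limits cannot be said. No paired analysis was possible because there is 1 group.

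Between the replicates' own lists, values ranged from 1556 to 1955 regions, 7 to 8 lists above and 2 to 4 below the background, 330 to 646 enriched and 224 to 391 depleted 6-mers, 0.889 to 0.976-fold intergenic, 1.12 to 1.2 for chromosome I, 0.967 to 1.10 for IV, 1.07 to 1.16-fold lincRNA and 0.438 to 1.78-fold antisense RNA. Odds ratios ranged from 1.36 to 2.28 for germline mitosis and meiosis, 0 to 1.36 for muscle, 0.278 to 1.21 for cuticle collagens and 0.799 to 2.12 for intestine.

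With the 500 regions of highest signal, 5' UTRs (1.87-fold), 3' UTRs (1.42-fold) and intergenic sequence (0.985-fold) lost the call. So did the central part of the autosomes (1.14). Chromosome IV (0.929) and lincRNA (2.99-fold) changed direction. For these 500 regions 3 lists were above and 1 below, with 269 enriched and 195 depleted 6-mers. Odds ratios were 0.927 for mitochondrial ribosomal proteins, 0 for vitellogenins and muscle and 1.69 for sperm. Without regions of the commonest width, intergenic sequence had 0.940-fold and lincRNA 1.66-fold; 7 lists were above and 1 below, with 381 enriched and 235 depleted 6-mers, and odds ratios of 1.34 for germline mitosis and meiosis, 1.06 for sperm and 0 for muscle. Against ranked sites, intergenic sequence had 1.47-fold, piRNA 0.819-fold and the operon candidates 0.998-fold; 5 lists were above and 0 below, with 0.834 for mRNA 3' end processing, 1.53 for chemosensory receptors, 1.16 for C-type lectins, 1.47 for F-box proteins and 2.20 for sperm. The wider list gave 1.72 for germline mitosis and meiosis and 0.472 for muscle. Unmerged rows gave 0.959 for mRNA 3' end processing and 1.61 for intestine, assignment within 500 bp and leaving out regions at small non-coding genes each gave 0 for mRNA 3' end processing, and a 100 bp distance gave lincRNA 1.19-fold. The Spearman rho was 0.658 over regions past the threshold in both replicates. For single gene lists, 164 comparisons set beforehand kept direction and call, 40 lost the call and 1 gained it, and of those added later 40 kept it and 12 lost it. The call was lost by the RNA exosome, heat shock and xenobiotic lists in the wider list, by mitochondrial ribosomal proteins with unmerged rows, and by the RNA exosome with every start within 1000 bp, where nuclear hormone receptors gained it. With the 500 regions of highest signal, only cytosolic ribosomal proteins, translation factors, the respiratory chain and chemosensory receptors kept it. Without regions of the commonest width it was lost by mitochondrial ribosomal proteins, the RNA exosome, the proteasome, heat shock proteins, stress regulators, C-type lectins, F-box proteins and xenobiotic enzymes. The direction reversed in 19 comparisons set beforehand and in 4 added later, given above. For gene lists against ranked sites, direction was taken relative to 1, which is not the neutral value of that fold.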

Other observations

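Of the tests in this part, the scan of symbol families and the test on tRNA genes whose sequence occurs once were chosen after the result was seen. The scan covered 183 families of gene symbols with at least 10 members. In this scan 5 families were above the background and 1 below it. The lin genes, a set of unrelated genes named for cell lineage phenotypes, had 13 of 47 bound (odds ratio 5.41, adjusted Fisher's exact p = 0.00036), and the zip family of basic leucine zipper genes 5 of 12 (10.1, adjusted exact p = 0.025). The str chemoreceptor family had 0 of 194 bound (adjusted exact p = 0.00019), and the other 3, rpl, rps and vha, are parts of fixed lists. Of the 38 genes annotated as snRNA with a summit, 10 were sls spliced-leader genes, whose signals had a median of 260.1.

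The tRNA genes were hit 18.1-fold more often than under placement. Reads shared among identical copies are a candidate explanation: genes whose exact sequence occurs once were hit in 12.9% of 140 cases and genes with repeated sequence in 25.8% of 472, a ratio of 0.497, just below the bound of 0.5 set for this explanation, with a 95% bootstrap interval from 0.287 to 0.740 that spans it. The ratio cannot decide, because the sources used here do not say how reads with several matches were treated. The 140 genes hit shared 121 regions, so a region can also count for several neighbouring genes. Exact copies do not account for the whole pattern, since genes whose sequence occurs once were still hit 10.02-fold over placement. Those over 1000 bp from any repeated tRNA gene were hit 8.39-fold (permutation p = 0.002 for both, the smallest possible). Similarity short of an exact match was not measured, so reads shared among near-identical tRNA genes stay open. Draws from the ranked list gave 39.9 tRNA genes against 140 observed, 3.51-fold (permutation p = 0.002). This argues against a property common to all ranked sites of these libraries. Most ranked sites lie below the threshold, so the draws cannot speak to a property of strong sites. Strong sites shared by many tagged proteins remain open because no mock or other-protein library was analysed here.

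Summits near gene ends could come from closely spaced genes or from non-coding genes. At ends over 1000 bp from any annotated protein-coding gene start the share was 2.02-fold over placement (permutation p = 0.002). This argues against neighbouring annotated starts as the whole source. Sites of initiation away from the annotated start, as in trans-spliced genes, can lie nearer to these ends and stay open. Without the summits at non-coding genes the 1934 others stood at 2.24-fold near those ends, and at 2.20-fold with placement kept off non-coding genes too (permutation p = 0.002 for both). Sites enriched near gene ends for any tagged protein stay open, since no mock library was analysed here, and no biological explanation was tested.

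Regions clustered around the tagged gene, mostly not touching it, and extra transgene copies are a candidate source. The median signal of ranked between-replicate regions 2 to 20 kb off the gene was at percentile 82.4 of chromosome windows on one side. On the other side it was at 87.7, and both lie between the bounds of 75 and 90 set for the test. With the pooled ranked list the values were 85.2 and 94.3. The gene with 2 kb either side stood at percentile 97.7 of the same 18 kb windows, and at 98.2 with the pooled list. By the bounds set beforehand the test gave no answer, because in neither list were both flanks above 90 or both below 75. Flank signal could not tell copy number and binding at the locus apart in any case. High flanks could come from binding there, and low flanks from a transgene shorter than the flanks. The extent of the transgene is also not given in the sources used here, and no untagged library was analysed. No biological explanation was tested.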
